A study of Homo sapiens with 6 samples.

How the data were processed

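The series holds 6 Ribo-seq samples of NCI-H1299 cells, 3 shControl and 3 shALDH18A1, grouped by the titles in the labels. The design text calls the control puro. The only values used here were those of a single table of the authors' own comparison, whose name refers to genes of differential translation efficiency. It has 15244 entries and no column of values per sample, so 0 such columns were left out. Per the submitters' processing notes, the tools were fastp 0.23.2, STAR 2.7.10a and featureCounts, with hg38 as genome build. The role and settings of each tool, the annotation, the counting's use of strand, any removal of ribosomal RNA reads, the footprint length range and any ribosome A-site offset are not given in the sources used here. Such choices can move the values: without strand, reads of overlapping genes cannot be told apart, and reads that map to several copies of a gene can be dropped or split.

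The deposited mean per gene is a normalized signal, a mean count on a size-factor scale, per the file headers; which libraries entered it is not stated. The deposited fold change and its SE are on a log scale, taken as log2 from the header layout, whose column order is that of DESeq2, although no source used here says that the authors ran it. The deposited statistic is a score that equals the fold change over its SE, with a largest difference of 1.49e-13. Each deposited p-value equals the two-sided normal p of that score, and the adjusted p-value is the Benjamini-Hochberg value, with a largest difference of 7.42e-06. A symbol that occurs more than once was kept with its smallest p, which left 15243 genes. The authors' own marks, 2310 up, 1408 down and 11526 stable, match an unadjusted p under 0.05 with a log2 fold change beyond 1 either way, with 0 exceptions. Of the 3718 marked entries, 107 had an adjusted p of 0.05 or more.

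The sources used here do not state the reference group, the design formula, the number of libraries in the fit, or whether the fold is of footprints or of footprints over RNA. Signs are therefore given as in the table, and no direction between shALDH18A1 and shControl was drawn from them.

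Genes were matched to the RefSeq annotation of GRCh38.p14 for names, types, coordinates and overlaps. Of the entries, 14700 matched by Entrez ID, 1 by symbol and 32 by an older symbol, and 511 did not match. Of the entries, 510 carry an Ensembl ID in place of a symbol, and 54 of the matched ones are not protein-coding. No genome sequence was used here. Overlaps were taken between the annotated gene spans.

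Genes were called at the deposited adjusted p under 0.05. Intervals of 95% are the deposited fold change with the normal quantile times its SE. A set of 30 gene lists, the thresholds, the tests and the rule for named genes were fixed before the data were examined. Each list was tested against all other genes with limma's cameraPR (limma 3.58.1 in R 4.3.3) on the deposited statistic, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 30 lists. The share of called members was tested with Fisher's exact test, two-sided. List medians were set against 100000 random lists of the same size drawn within 10 bins of abundance (two-sided, smallest possible p 2e-05). Other work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

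The named genes were ALDH18A1, the 12 largest increases and the 12 largest decreases among called genes at or above the median abundance, and up to 4 members of each list with the smallest p. The largest changes were taken among genes with a symbol that are protein-coding where the type is known. Lists with at most 5 called members had these named in full. The rule gave 139 genes. Genes named outside the rule are said to be so. A few genes that the rule names, and a gene family, are not reported here.

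The planned tests for counts per sample did not apply, since the table holds a finished comparison. The planned rule for that case was used, which counts the authors' adjusted p and fold changes as deposited. The planned tests of RNA abundance and of classes of regulation need columns that the table does not have, and were not run. Alternatives tried were other thresholds on the adjusted p, fold minimums of 1.5-fold and of 1 on the log2 scale, Benjamini-Yekutieli and Bonferroni adjustment, centring on the median, protein-coding genes only, every entry in place of 1 per symbol, and genes at or above the median abundance. For lists they were a preset correlation of 0.05, a rank-based test, the fold change as statistic, random lists and genes at or above the median abundance. The authors' marks and the lists without solute carrier genes were added after seeing the data.

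The depth of each library is unknown, so precision rests on the deposited SE, whose median was 0.178, with 0.123 at or above the median abundance and 0.341 below it. The steps were tested on simulated data before use. In a simulated list shift over 15243 genes, 5 of 6 lists moved by 0.75 SD of the statistic were recovered with their direction, and 0 of 21 lists that shared no gene with them were called. The statistics were shuffled over genes for this, which removes correlation between genes and any trend with abundance. The simulation therefore cannot show how often these would cause false list calls. In simulated statistics for 15243 genes, 195 of 200 genes moved by 5 SE were called (97.5%), with 9 unmoved genes called.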

Results

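Ribosome footprint sequencing (Ribo-seq), which reads the stretches of mRNA covered by translating ribosomes, was carried out in NCI-H1299 cells, a human non-small cell lung carcinoma line that lacks p53. The 6 samples comprised 3 controls (shControl) and 3 carrying a short hairpin RNA against ALDH18A1 (shALDH18A1), the gene for the proline biosynthesis enzyme P5CS. The comparison asked which mRNAs are translated differently after a knockdown aimed at P5CS, which the series studies as an RNA-binding protein. The values came from a single comparison table made by the authors, which gives each of 15243 genes a mean normalized count, a log fold change with its standard error (SE) and p-values. Values per sample were not analysed here, so the depth of each library is unknown and no replicate values or counting intervals are given. Mean normalized counts in the authors' deposited table ran from 0.814 to 369476, with a median of 150.2.

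The sources used here do not state the reference group of the comparison. Higher and lower therefore give the sign of the fold change in the authors' deposited table, not a direction between shALDH18A1 and shControl. Nor do they state whether the fold is one of footprints or of translation efficiency, and base 2 was taken from the column layout. Genes were called at an adjusted p under 0.05, and ± gives the table's own SE.

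ALDH18A1, the targeted gene, was not called, at a log2 fold change of −0.19 ± 0.12 in the authors' deposited table (adjusted p = 0.173). Around it the table held broad differences: 4411 genes were called higher and 4488 lower. All 13 mitochondrially encoded mRNAs were higher, by a median of 3.08 on the log2 scale, and so were most chaperones of the endoplasmic reticulum (ER). Most proteasome subunits, aminoacyl-tRNA synthetases and translation initiation factors were lower, by smaller amounts. At an adjusted p under 0.05, none of these lower planned lists differed from random lists matched on abundance, whereas the mitochondrially encoded genes and ER chaperones did. The matrix gene THBS1 was among the highest and the integrin gene ITGB3 among the lowest.

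ALDH18A1 (Entrez ID 5832) lies on chromosome 10 from 95605941 to 95656711 in GRCh38. Its mean normalized count in the authors' deposited table was 846, and the 95% interval of its log2 fold change ran from −0.44 to 0.05. Taken as log2, the interval allows a change of at most 1.35-fold either way, and taken as a natural log at most 1.55-fold.

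The called genes made up 58.4% of the 15243, and 49.6% of them were higher. Of the genes called in the authors' deposited table, 2244 were higher and 1367 lower by at least 1 on the log2 scale, so that 62.1% of these larger changes were higher. Among genes at or above the median abundance the called share was 71.8%, against 45.0% below it, where the median SE was 0.341 rather than 0.123. With the adjustment redone over genes at or above the median abundance alone, 43.1% of those called were higher. Abundance and fold change were weakly and negatively related across genes (Spearman's rho −0.12), which are not independent replicates. The median log2 fold change went from 0.27 in the least abundant of 10 equal bins of genes to −0.11 in the most abundant bin.

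**Figure D1:**
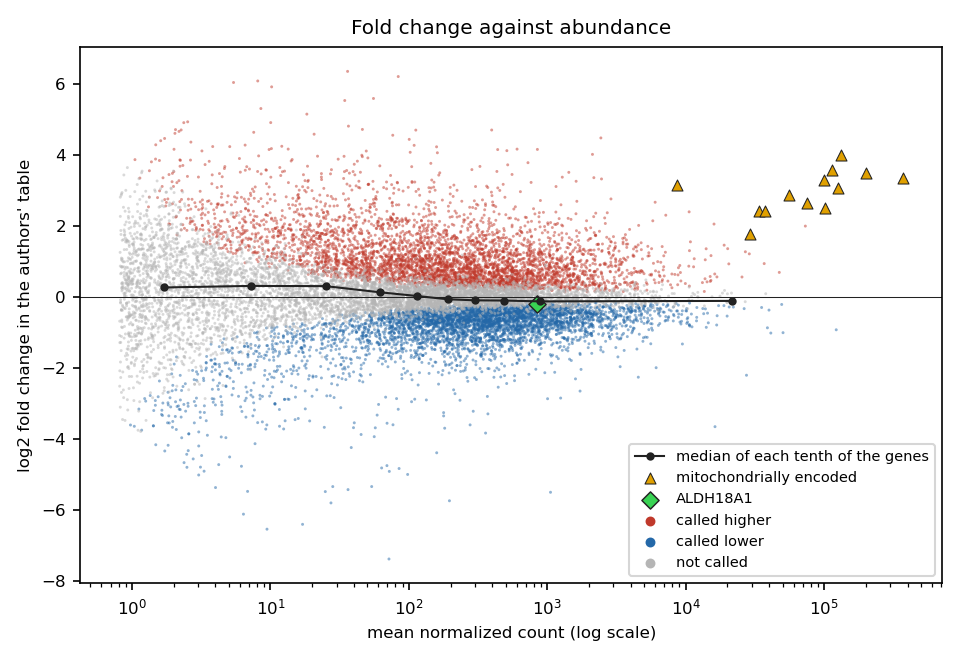
Log2 fold change of each gene in the authors' deposited table (vertical axis) against its mean normalized count (horizontal log axis), with the medians of 10 abundance bins as a line. The 13 mitochondrially encoded genes (triangles) lie at high counts and at 1.78 or above, and ALDH18A1 (diamond) lies at −0.19.

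TMEM158, a transmembrane protein gene on chromosome 3 (45224466 to 45226287), had the largest increase among genes at or above the median abundance, higher by 4.71 ± 0.19 on the log2 scale in the authors' deposited table, a 26.1-fold difference. It was followed in the authors' deposited table by THBS1, which encodes the matrix glycoprotein thrombospondin (4.48 ± 0.14), and SEMA6B, a transmembrane semaphorin (4.23 ± 0.38). The growth factor gene MDK (4.17 ± 0.20), the retrotransposon-derived imprinted gene PEG10 (4.16 ± 0.13) and the lipoprotein receptor gene LRP8 (4.16 ± 0.11) lay close together in the authors' deposited table. The zinc finger gene ZNF404 (4.13 ± 0.22), TM4SF18 (4.07 ± 0.18) and EMP1, an epithelial membrane protein gene (4.02 ± 0.11), came next in the authors' deposited table. The authors' deposited table then listed MT-ATP6, a mitochondrially encoded ATP synthase subunit (4.01 ± 0.39), BCAM, a cell adhesion molecule (3.79 ± 0.20), and PXDN, a matrix peroxidase (3.73 ± 0.13). All 12 had adjusted p of at most 7.72e-24 in the authors' deposited table, the value of MT-ATP6. The annotated gene span of THBS1 overlaps that of FSIP1 by 2027 bases, and that of MDK overlaps CHRM4 by 49 bases. The counting's use of strand is not given, so how far shared reads move either value is unknown.

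ABCC9, a subunit of ATP-sensitive potassium channels on chromosome 12 (21797389 to 21941426), had the largest decrease among these abundant genes, at −5.74 ± 0.30 in the authors' deposited table, a 53.6-fold difference. TNFRSF9, a costimulatory receptor of the tumour necrosis factor family, stood at −5.50 ± 0.20 in the authors' deposited table, at a mean normalized count of 1054. The leukocyte integrin gene ITGAM (−4.39 ± 0.21), the adhesion molecule gene MCAM (−3.84 ± 0.24) and CCDC148 (−3.70 ± 0.19) followed in the authors' deposited table. ANKRD1, a target of the coactivator YAP and the most abundant of these genes, was at −3.66 ± 0.17 in the authors' deposited table with a mean normalized count of 16252. The small GTPase gene RRAD (−3.60 ± 0.13), the integrin gene ITGB3 (−3.35 ± 0.14) and the cyclin E gene CCNE1 (−3.29 ± 0.11) were also among the lowest in the authors' deposited table. DYSF, which acts in membrane repair (−3.22 ± 0.11), the hemidesmosome collagen gene COL17A1 (−2.91 ± 0.18) and C15orf48 (−2.87 ± 0.15) completed the 12 in the authors' deposited table. The largest adjusted p among them in the authors' deposited table was 7.68e-55, that of MCAM.

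**Figure D2:**
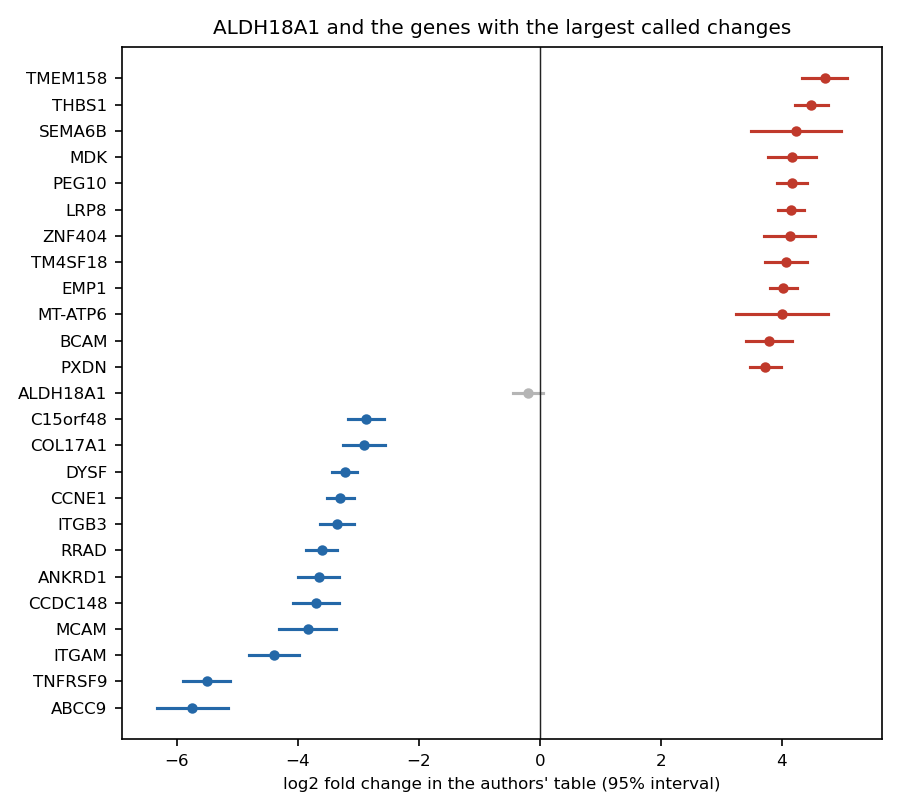
Log2 fold change in the authors' deposited table (horizontal axis, points) with its 95% interval (bars) for ALDH18A1 and the 12 largest increases and 12 largest decreases among abundant called genes. The increases lie between 3.73 (PXDN) and 4.71 (TMEM158), the decreases between −5.74 (ABCC9) and −2.87 (C15orf48), and the interval of ALDH18A1 includes 0.

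Of the 30 gene lists, 12 were shifted against all other genes at an adjusted p under 0.05 (limma's preset-correlation list test on the table's statistic, correlation 0.01), 6 higher and 6 lower. A correlation estimated from samples could not be had without values per sample. With a preset correlation of 0.05 only the mitochondrially encoded genes, the ER chaperones, the proteasome and the aminoacyl-tRNA synthetases remained called. Against 100000 random lists matched on abundance, only the mitochondrially encoded genes and the ER chaperones differed (adjusted p = 0.000600 and 0.00960). With the fold change in place of the statistic only the mitochondrially encoded genes were called.

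**Figure D3:**
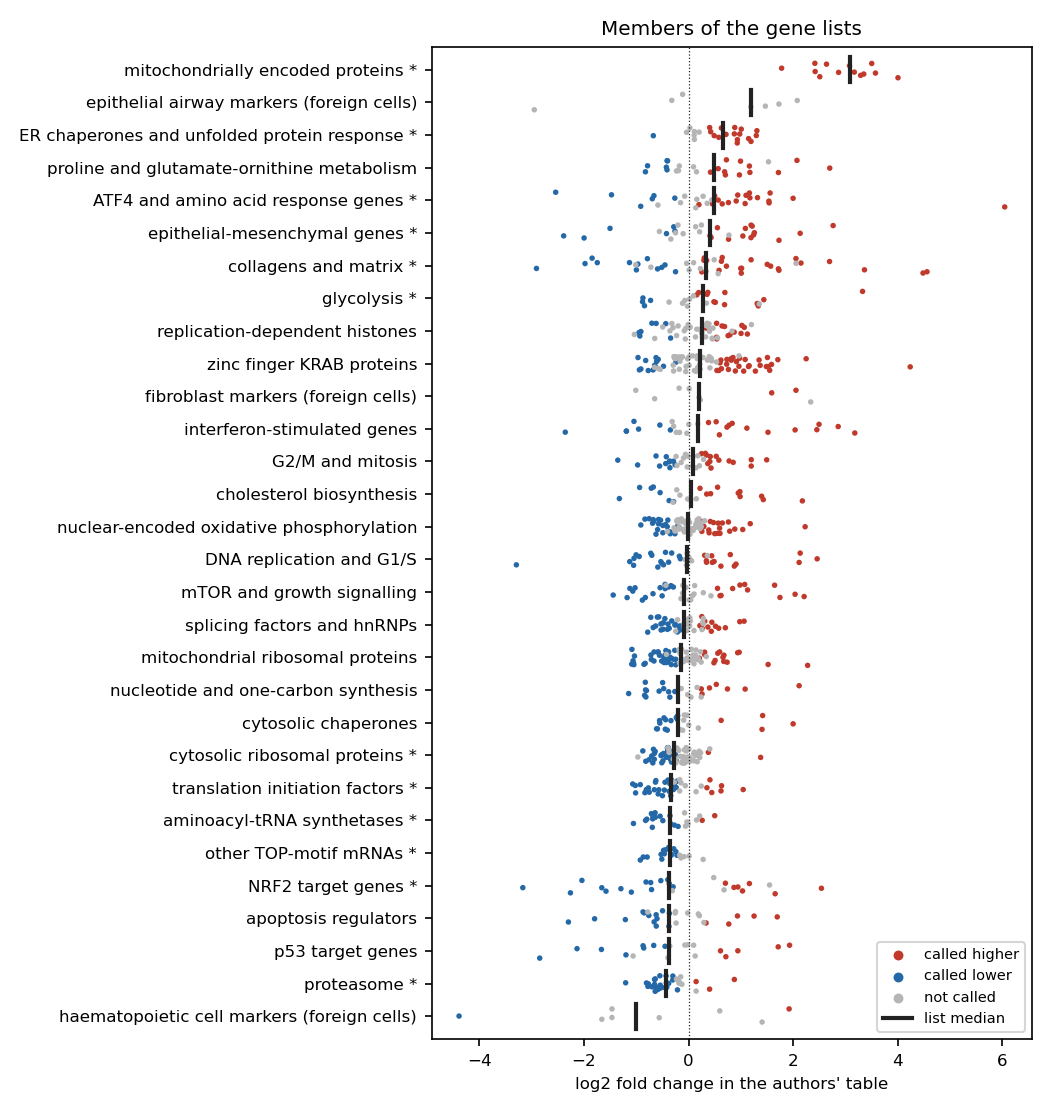
Log2 fold changes in the authors' deposited table (horizontal axis) of the members of each of the 30 gene lists, sorted by list median (bars); colours give genes called higher, lower or not called, and an asterisk the 12 lists called in the list test. The medians run from 3.08 for the mitochondrially encoded genes to −1.01 for the haematopoietic markers, a list of 8 measured genes that was not called.

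The mitochondrially encoded genes, which specify core subunits of the respiratory chain and ATP synthase, had the clearest shift. All 13 were called higher, also when adjusted over the list alone, and the list test gave an adjusted p of 5.59e-05 (0.00198 at a preset correlation of 0.05). In the authors' deposited table they ranged from 1.78 ± 0.15 for MT-ND4L to 4.01 ± 0.39 for MT-ATP6, with MT-ND6 at 2.42 ± 0.21 and MT-ATP8 at 2.42 ± 0.22. MT-CO1, the most abundant gene, stood at 3.35 ± 1.02 in the authors' deposited table, and together the 13 held 13.4% of the mean normalized counts; MT-CO1 was named after its value was seen. The SEs of these named mitochondrial genes all lay above 0.10, the median SE in the most abundant of the 10 bins of genes. MT-ATP6 and MT-ATP8 overlap, as do MT-ND4L and MT-ND4, which leaves the split of their reads uncertain. The nuclear-encoded subunits of the same complexes did not shift as a group: of 77 measured, 21 were higher, 21 lower and 35 not called, with the same counts adjusted over the list alone (adjusted p = 0.955). Their median was −0.01 and their mean 0.02, and the test's direction was higher, so these differ in sign. NDUFA9 (2.23 ± 0.10), NDUFB11 (1.18 ± 0.12), UQCRC1 (1.04 ± 0.11) and ATP5F1A (0.59 ± 0.04) were the members with the smallest p in the authors' deposited table, and NDUFB11 overlaps RBM10. Mitochondrial ribosomal proteins went more often lower, with 15 higher, 35 lower and 29 not called of 79 (16 and 36 adjusted over the list alone), but the list was not called (median −0.15, adjusted p = 0.108). MRPL15 (−1.05 ± 0.07), MRPS16 (−1.08 ± 0.09) and MRPS23 (−0.71 ± 0.07) were lower in the authors' deposited table, whereas MRPL36 was higher at 2.28 ± 0.19 and overlaps NDUFS6.

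Genes of the ER folding machinery were mostly higher. Of 24 measured ER chaperone and unfolded protein response genes, 17 were higher, 1 lower and 6 not called, and 17 and 1 adjusted over the list alone. The median was 0.66, with an adjusted p of 0.000451 (0.0239 at a preset correlation of 0.05). Membrane and secreted protein families, chosen after the largest changes were seen, had a similar median of 0.69 over 829 genes. The shift is thus not particular to genes of ER folding. The protein disulfide isomerase genes P4HB (1.31 ± 0.09) and PDIA4 (0.88 ± 0.09) and the cochaperone genes DNAJB11 (1.15 ± 0.09) and SDF2L1 (1.29 ± 0.12) had the smallest p of the list in the authors' deposited table. HSPA5, the central ER chaperone, was not called at 0.11 ± 0.14 in the authors' deposited table, and DNAJB9 was the only member called lower (−0.67 ± 0.21). Both of these were named after their values were seen.

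Matrix and mesenchymal genes went both ways with more increases. Of 44 measured collagen and matrix genes, 22 were higher, 12 lower and 10 not called, with 22 and 12 adjusted over the list alone (median 0.34). The list's adjusted p of 0.00827 became 0.123 at a preset correlation of 0.05. LOXL2, a collagen crosslinking enzyme (3.36 ± 0.12), and the laminin gene LAMB1 (1.73 ± 0.08) were higher in the authors' deposited table, as was THBS1, whereas COL17A1 was lower. Epithelial-mesenchymal genes counted 14 higher, 6 lower and 9 not called of 29, also when adjusted over the list alone (median 0.41), and the adjusted p of 0.0402 became 0.224 at a preset correlation of 0.05. TGFB1 (2.76 ± 0.09), the protease gene MMP14 (1.04 ± 0.09) and the fibronectin gene FN1 (1.20 ± 0.10) were higher and TGFBI lower (−1.999 ± 0.13) in the authors' deposited table. FN1 overlaps ATIC.

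Of 24 glycolysis genes, 12 were higher, 4 lower and 8 not called, also when adjusted over the list alone (median 0.27, adjusted p = 0.0159). The call ended at a preset correlation of 0.05 (adjusted p = 0.123). The glucose transporter gene SLC2A1 had the smallest p of the list, at 3.33 ± 0.11 in the authors' deposited table, where the lactate transporter genes SLC16A1 and SLC16A3 were at 1.33 ± 0.09 and 1.31 ± 0.14. The phosphofructokinase gene PFKM was higher at 1.44 ± 0.08 in the authors' deposited table, and it overlaps SENP1 as SLC16A3 overlaps CSNK1D. With solute carrier genes left out of every list, a setting chosen after seeing the data, the glycolysis list was not called (adjusted p = 0.512). Cholesterol biosynthesis genes moved apart, with 10 higher, 7 lower and 6 not called of 23, also over the list alone (median 0.04, adjusted p = 0.287). HMGCS1 was lower (−1.32 ± 0.07) and CYP51A1 (1.43 ± 0.08), INSIG1 (0.99 ± 0.07) and TM7SF2 (2.18 ± 0.16) higher in the authors' deposited table.

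Lists of the translation machinery leaned lower, but none differed from random lists matched on abundance. Of 82 measured cytosolic ribosomal protein genes, 40 were lower, 2 higher and 40 not called, or 38 and 2 adjusted over the list alone (median −0.27, adjusted p = 0.0402). RPL11 (−0.88 ± 0.09), RPL6 (−0.68 ± 0.09) and RPS4X (−0.71 ± 0.11) were lower in the authors' deposited table, and RPLP2 higher at 1.38 ± 0.12. Other mRNAs with a terminal oligopyrimidine (TOP) motif, the 5′ element that ties translation to growth signals, were lower in 15 of 20 with none higher, or 16 adjusted over the list alone (median −0.36, adjusted p = 0.00827). The elongation factor genes EEF1A1 (−0.92 ± 0.10) and EEF2 (−0.87 ± 0.10), IPO5 (−0.79 ± 0.06) and VIM (−0.28 ± 0.04) were examples in the authors' deposited table. At a preset correlation of 0.05 neither list was called (adjusted p = 0.311 for the ribosomal proteins and 0.0909 for the TOP mRNAs). Against random lists matched on abundance the adjusted p was 0.167 and 0.236, in the same order. Those random lists had a median of −0.11 for each. The rank-based list test called both lists lower (adjusted p = 0.000808 and 0.000732). Ribosomal protein and EEF1A1 reads can be shared with pseudogenes, which leaves these values uncertain.

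Initiation factors were lower in 26, higher in 6 and not called in 7 of 39, or 28 and 6 adjusted over the list alone. Their median was −0.34 with an adjusted p of 0.0112, which became 0.135 at a preset correlation of 0.05. Against random lists matched on abundance, which had a median of −0.10, the adjusted p was 0.184, and in the rank-based list test 0.00160. EIF4G2 (−0.63 ± 0.05), EIF4G1 (−0.58 ± 0.05), EIF2S1 (−1.07 ± 0.12) and the cap-binding gene EIF4E2 (−1.01 ± 0.11) were lower in the authors' deposited table, and EIF2S1 overlaps GPHN. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, were lower in 15, higher in 2 and not called in 6 of 23, also adjusted over the list alone (median −0.36). Their adjusted p was 0.00243, with 0.0459 at a preset correlation of 0.05 and 0.00173 in the rank-based list test. It was 0.236 against random lists matched on abundance, which had a median of −0.11. GARS1 (−0.80 ± 0.06), TARS1 (−0.64 ± 0.06) and NARS1 (−0.68 ± 0.07) were lower in the authors' deposited table. Splicing factors and hnRNPs did not shift together, with 12 higher, 21 lower and 16 not called of 49, also over the list alone (median −0.08, adjusted p = 0.565). SRSF6 (−0.72 ± 0.06) and SF3A1 (−0.60 ± 0.05) were lower and SRSF7 (0.58 ± 0.06) and SF3B3 (0.45 ± 0.04) higher in the authors' deposited table, and SF3A1 overlaps CCDC157.

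Proteasome subunits were lower in 22, higher in 3 and not called in 6 of 31, or 24 and 3 adjusted over the list alone. The median was −0.43 with an adjusted p of 0.000490 (0.0340 at a preset correlation of 0.05). PSMA1 (−1.20 ± 0.09), PSMD12 (−0.81 ± 0.08) and PSMC6 (−0.64 ± 0.06) were lower in the authors' deposited table, and PSMA4 higher at 0.88 ± 0.08. Targets of NRF2, the regulator of antioxidant genes, were lower in 14, higher in 7 and not called in 4 of 25, also over the list alone (median −0.37). Their adjusted p of 0.00827 became 0.0993 at a preset correlation of 0.05. The thioredoxin reductase gene TXNRD1 (−2.26 ± 0.06), the heme oxygenase gene HMOX1 (−2.04 ± 0.14), the glutathione synthesis gene GCLM (−1.66 ± 0.12) and OSGIN1 (−1.58 ± 0.11) were lower in the authors' deposited table. TXNRD1 overlaps EID3 and OSGIN1 overlaps NECAB2. Cytosolic chaperones numbered 4 higher, 12 lower and 7 not called of 23, also over the list alone (adjusted p = 0.643). Their median was −0.21 and the test pointed lower, whereas the mean was 0.00365. The heat shock genes HSP90AA1 (2.00 ± 0.14), HSPA1A (1.40 ± 0.11) and HSPA1B (1.42 ± 0.12) were higher and the chaperonin gene CCT5 lower (−0.56 ± 0.07) in the authors' deposited table. HSPA1A and HSPA1B are near-identical copies and HSP90AA1 overlaps WDR20, so these values are uncertain.

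Among proline and glutamate-ornithine genes, the pathway of the targeted enzyme, 12 were higher, 6 lower and 6 not called of 24, or 13 and 6 adjusted over the list alone. The median was 0.49 and the list was not called (adjusted p = 0.108). The glutamine transporter gene SLC1A5 (2.07 ± 0.12), the prolyl hydroxylase gene P4HA1 (1.72 ± 0.15) and the arginase gene ARG2 (6.50-fold, SE 0.25 on the log2 scale) were higher and the glutamate dehydrogenase gene GLUD1 lower (−0.40 ± 0.05) in the authors' deposited table. ARG2 overlaps GPHN and VTI1B, GLUD1 overlaps SHLD2, and GLUD1 shares close sequence with GLUD2. ATF4 and amino acid response genes were higher in 18, lower in 6 and not called in 8 of 32, or 19 and 6 adjusted over the list alone (median 0.48). Their adjusted p of 0.0422 became 0.236 at a preset correlation of 0.05, and 0.155 without solute carrier genes. The serine synthesis genes PSAT1 (1.56 ± 0.09) and PHGDH (1.32 ± 0.11) and the serine hydroxymethyltransferase gene SHMT2 (1.08 ± 0.10) were higher in the authors' deposited table. The transcription factor gene ATF3 was lower there, at −2.54 ± 0.14. SHMT2 overlaps COXFA4L2.

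Cell cycle lists were not called and held members at both ends. DNA replication and G1/S genes numbered 13 higher, 17 lower and 10 not called of 40, or 14 and 17 adjusted over the list alone (median −0.03, adjusted p = 0.709). The thymidylate synthase gene TYMS (2.11 ± 0.08) and the cyclin gene CCND3 (2.46 ± 0.16) were higher and RFC2 (−1.13 ± 0.09) lower in the authors' deposited table, as was CCNE1. TYMS overlaps ENOSF1. G2/M and mitosis genes numbered 14 higher, 11 lower and 13 not called of 38, also over the list alone (median 0.08, adjusted p = 0.754). CDC20 (1.20 ± 0.11) and KIF20A (1.20 ± 0.12) were higher and UBE2C (−0.97 ± 0.07) and BUB3 (−0.62 ± 0.06) lower in the authors' deposited table, and KIF20A overlaps CDC23. Replication-dependent histones were called in 14 higher and 7 lower of 55, or 12 and 7 adjusted over the list alone (median 0.25, adjusted p = 0.614). H2AC16 (1.12 ± 0.17) and H2AC14 (1.00 ± 0.19) were higher and H2AC18 (−0.93 ± 0.20) and H2BC12 (−0.62 ± 0.14) lower in the authors' deposited table, and reads shared between histone copies leave them uncertain. Nucleotide and one-carbon synthesis genes numbered 7 higher, 12 lower and 5 not called of 24, or 8 and 12 adjusted over the list alone (median −0.20, adjusted p = 0.438). The purine synthesis genes ADSL (−1.15 ± 0.10), GART (−0.82 ± 0.05) and ADSS2 (−0.84 ± 0.07) were lower in the authors' deposited table. ADSL overlaps SGSM3 and ADSS2 overlaps CATSPERE.

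Known p53 targets, measured in a line without p53, were higher in 5, lower in 8 and not called in 7 of 20, or 5 and 9 adjusted over the list alone (median −0.38, adjusted p = 0.108). PLK2 (−2.85 ± 0.13), GADD45A (−2.13 ± 0.10) and the cyclin-dependent kinase inhibitor gene CDKN1A (−1.67 ± 0.13) were lower and the death receptor gene FAS higher (1.93 ± 0.14) in the authors' deposited table. FAS overlaps ACTA2. Apoptosis regulators numbered 5 higher, 13 lower and 8 not called of 26, also over the list alone (median −0.37, adjusted p = 0.193). The caspase inhibitor gene XIAP (−1.80 ± 0.16), BIK (−2.30 ± 0.27) and MCL1 (−0.38 ± 0.05) were lower and BID (0.93 ± 0.12) higher in the authors' deposited table. Of 38 mTOR and growth signalling genes, 11 were higher, 15 lower and 12 not called, also over the list alone (adjusted p = 0.895). Their median was −0.08 and the test pointed lower, whereas the mean was 0.06. The receptor genes EGFR (2.21 ± 0.13) and IGF1R (1.65 ± 0.12) were higher in the authors' deposited table.

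Interferon-stimulated genes numbered 13 higher, 7 lower and 7 not called of 27, also over the list alone (median 0.18, adjusted p = 0.565). IFI6 (2.50 ± 0.17) and IFIT1 (3.18 ± 0.24) were higher and ISG20 (−2.36 ± 0.24) and HERC5 (−1.04 ± 0.12) lower in the authors' deposited table, and IFIT1 overlaps LIPA. KRAB zinc finger genes, which encode transcriptional repressors, were higher in 30, lower in 13 and not called in 36 of 79, also over the list alone (median 0.21, adjusted p = 0.217). ZNF300 (1.55 ± 0.17), ZNF224 (1.49 ± 0.17), ZNF45 (1.35 ± 0.16) and ZNF331 (1.28 ± 0.18) were higher in the authors' deposited table, and ZNF300 overlaps IRGM. The share of called members, 58.4% over all genes, was higher among initiation factors (82.1%), mitochondrially encoded genes (100%) and NRF2 targets (84.0%). It was lower among histones (38.2%) and airway markers (0%), by Fisher's exact test (two-sided, adjusted p = 0.0269 for each except 0.0489 for NRF2 targets). These shares were not matched on abundance, with which calls rose, and the airway markers had a median normalized count of 1.81.

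Markers of other cell types were mostly near the lower end of the counts, and their 3 lists were not called. Of 8 haematopoietic markers, ITGAM was lower and CD14, at a mean normalized count of 2.92, higher by 1.92 ± 0.73 in the authors' deposited table, with 1 and 1 also over the list alone (median −1.01, adjusted p = 0.348). CD14 overlaps TMCO6. Of 9 fibroblast markers, PDGFRB (1.59 ± 0.30) and COL6A3 (2.05 ± 0.82) were higher in the authors' deposited table at mean normalized counts of 26.1 and 3.92. A single fibroblast marker stayed called when adjusted over the list alone (median 0.20, adjusted p = 0.702). Of 7 airway markers none was called, with a median of 1.19 and an adjusted p of 0.895. The largest mean normalized count among the airway genes with the smallest p was 4.70 for MUC5B in the authors' deposited table.

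The p-values measure only the spread between the libraries that entered the authors' fit, and the labels do not say whether the replicates came from separate cultures. List tests treat genes as if nearly independent, which co-regulated genes are not.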

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

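The authors' marks and the lists without solute carrier genes were chosen after seeing the data; all other alternatives were planned. Genes called higher numbered 4411, against 2244 with a log2 fold change of at least 1, 2338 with Bonferroni adjustment, 2390 among genes at or above the median abundance and 2310 with the authors' marks. Genes called lower numbered 4488, against 2935 with a fold of at least 1.5, 1367 with a log2 fold change of at least 1, 2366 with Bonferroni adjustment and 1408 with the authors' marks. Apart from the authors' marks, which rest on an unadjusted p and include 107 entries with an adjusted p of 0.05 or more, these sets are smaller by construction. The share of higher calls was 49.6%, against 62.1% with a minimum of 1 and 43.1% at or above the median abundance. For that last setting the adjustment was redone over those genes alone. Both counts stayed within 1.5 times of their value under the other planned settings. Of the 139 named genes, 2 lost their call with Benjamini-Yekutieli and 4 with Bonferroni adjustment (H2AC18, H2BC12, CD14 and COL6A3), and none changed side when centred; no direction was reversed. ALDH18A1 was not called under any of these. From 6 lists called higher and 6 lower, the counts fell to 1 and 0 with the fold change as statistic, 2 and 2 with a preset correlation of 0.05, and 2 and 0 against random lists. The rank-based test left 3 higher, losing matrix, glycolysis and epithelial-mesenchymal genes, and lost the NRF2 list. At or above the median abundance 3 lists were left lower, losing ribosomal proteins, TOP mRNAs and initiation factors, and the ATF4 list lost its call. Without solute carrier genes the glycolysis and ATF4 lists lost theirs. The cause was not tested, beyond fewer genes at or above the median abundance and the wider null of a higher correlation. No paired analysis was possible because the table has no values per sample. For the same reason the edgeR and DESeq2 fits, leaving out each replicate, other pseudocounts, an estimated correlation, tests of RNA or of classes of regulation, and other splits of the samples were not run, and it is not known whether a single library decides any call. The genes at or above the median abundance held too few cell type markers to test those 3 lists.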

Other observations

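The families and the NF-kB, immediate early and YAP lists were chosen after the largest changes had been seen, and 80 genes already seen were left out of them. Their example genes were named after their values were seen, and the tests on ALDH18A1 and on the spread of the mitochondrial folds were chosen only after those values were seen. Signs are again those of the authors' deposited table. Protocadherins, cell adhesion proteins of clustered genes, moved together: 55 of 60 were called higher and none lower, with a median log2 fold change of 2.12 (adjusted p = 2.27e-17). PCDHB6 (3.11 ± 0.11) and PCDHGA3 (2.31 ± 0.12) were examples in the authors' deposited table. Reads shared between these similar and overlapping genes leave single values, the count of calls and the p-value of the list uncertain. Solute carriers were higher in 135 and lower in 24 of 275, and genes named as transmembrane proteins higher in 107 and lower in 15 of 186 (adjusted p = 7.22e-06 for each). Relatives of the LDL receptor (8 of 11 higher, LRP5 at 2.26 ± 0.11 in the authors' deposited table), potassium channels (25 of 61) and G protein-coupled receptors (19 of 33) were also shifted higher (adjusted p = 2.67e-05, 0.0295 and 0.00553). Potassium channels, at a median normalized count of 3.43, had a low share of called members (41.0%, Fisher's exact test, adjusted p = 0.0458). Ephrin receptors (0.0374) and Golgi galactosyltransferases (0.0121) were shifted higher in the list test as well. Semaphorins (0.0416), laminin chains (0.0179) and ABC transporters (0.0362) passed this test but not random lists matched on abundance (adjusted p = 0.209, 0.342 and 0.0797). Collagen chains (adjusted p = 0.661), claudins (0.759), plexins (0.586), integrins (0.147), ADAM proteases (0.340) and tetraspanins (0.150) missed the threshold in the list test. Ubiquitin-conjugating enzymes were lower in 24 of 35, with a median of −0.67 (adjusted p = 3.39e-05) and UBE2H at −1.27 ± 0.11 in the authors' deposited table. DEAD-box helicases were lower in 24 of 36, with a median of −0.46 (adjusted p = 9.97e-05) and DDX21 at −0.96 ± 0.05 in the authors' deposited table. Proteasome subunits (29 of 48 lower, adjusted p = 0.000996) passed too, and also against the matched random lists (adjusted p = 0.0249). The planned list of 31 proteasome genes missed the threshold against its matched random lists (adjusted p = 0.0860 over the 30 planned lists). Initiation factors (33 of 54 lower, 0.0374), chaperonin subunits (6 of 8 lower, 0.0491), ubiquitin-specific proteases (0.0310) and protein phosphatase subunits (0.0175) were shifted lower in the list test but not against the matched random lists (adjusted p = 0.115, 0.342, 0.0903 and 0.165). Kinesins (0.145), hnRNPs (0.433), RNA polymerase subunits (0.203), Kelch-like proteins (0.292), SR proteins (adjusted p = 0.757), TBC domain proteins (0.731) and cyclin-dependent kinases (0.757) missed the threshold. Adjusted p-values are over the 37 lists and families of this part, by the preset-correlation list test at a correlation of 0.01 unless another is named. Values at a correlation of 0.05, at which most calls of the planned lists ended, are not given for them.

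TNFRSF9, a target of NF-kB, stood among the lowest genes, so the remaining NF-kB targets were tested as a list. Of 27 measured, 13 were lower and 7 higher, with a median of −0.52. The limma list test gave 0.00278 before and an adjusted p of 0.00934 after adjustment. NFKB1 (−1.28 ± 0.07), NFKB2 (−1.32 ± 0.06), RELB (−1.29 ± 0.12) and TNFAIP3 (−2.19 ± 0.18) were lower and IER3 (1.29 ± 0.19) and ICAM1 (0.90 ± 0.11) higher in the authors' deposited table. A difference in NF-kB output between the groups is a hypothesis that this result is consistent with, but whether it lies in RNA or in translation cannot be read from this table. Immediate early genes were not shifted (34 measured, median 0.10, adjusted p = 0.757). YAP and TEAD targets had a median of 0.75, with 14 higher and 5 lower of 22, and missed the threshold in the list test (adjusted p = 0.0827) but passed it against matched random lists (adjusted p = 0.00214) and in the share of called members (Fisher's exact test, adjusted p = 0.0458). CCN1 (1.28 ± 0.14) and CCN2 (1.91 ± 0.19) were higher and AMOTL2 (−1.18 ± 0.05) lower in the authors' deposited table, and ANKRD1, left out as already seen, was at −3.66.

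ALDH18A1 was not called although it is the targeted gene. If the fold is a log2 fold of footprints, a knockdown of at least 1.5-fold is argued against, since the largest change within the gene's 95% interval was then 1.35-fold; on a natural log scale it was 1.55-fold and excludes no such knockdown. If the fold is a log2 translation efficiency from 12 libraries of equal depth, counting alone would set a lower bound on the SE, and 36.3% of 5128 genes with means of 20 to 200 lay below that bound. For a contrast over 6 libraries 0.7995% lay below, which does not exclude that reading but does not single it out, since noisier designs also pass a lower bound. A weaker knockdown, an efficiency that stays level while the RNA falls, libraries of unequal depth and a fold on a natural log scale, where 0.410% of the genes lay below the 12-library bound, stay open.

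All 13 mitochondrially encoded genes were higher, along with membrane and secreted protein families taken as a whole. Among these families, collagen chains (7 higher and 11 lower of 32, median −0.01) and plexins (3 higher and 2 lower of 9, median −0.13) were exceptions. A single fold shared by all 13 is argued against by their spread (heterogeneity chi-square 58.2 on 12 degrees of freedom, p = 4.73e-08). Over the 8 that overlap no other gene a single fold cannot be told apart from differing folds (heterogeneity chi-square, p = 0.143), and whether reads shared at the overlaps make the spread over all 13 was not tested. A change in the amount of mitochondrial RNA or ribosomes need not give a single fold, so the spread cannot decide on it and it stays open. Better recovery of membrane-bound ribosomes in 1 group, a technical candidate, predicts membrane and secreted families above soluble ones, and a biological change in the translation of these mRNAs, which stays open and untested, predicts the same. The medians were 0.69 for 829 genes and −0.24 for 561, a difference of 0.93 (permutation p = 1e-05, the smallest possible, over genes that are not independent) that was positive in 10 of 10 abundance bins (0.45 to 1.21).

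KRAB zinc finger genes had a positive median of 0.21, although the list was not called. The trend of fold change with abundance is a candidate explanation: random lists matched on abundance held 37.8% of the list's shift from the median of all genes (0.02), and the list missed the threshold against them (resampling of 100000 random lists, a permutation test, p = 0.378). The trend and a shift of its own cannot be told apart for this list, since its members spread widely, and a biological explanation was not tested.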
